A study of Mus musculus with 24 samples.

How the data were processed

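Stool was taken from mice of 4 groups, named control, model, SMD and Prednisone, and 6 stool samples per group were labelled for sequencing, which gives 24 samples. Per the labels' protocols, DNA was extracted with a stool DNA kit, the V3-V4 part of the bacterial 16S rRNA gene was amplified with universal bacterial primers, and the amplicons were sequenced as paired reads on a NovaSeq instrument. The 16S rRNA gene is present in all bacteria and archaea and in the plastids and mitochondria of eukaryotes, so that primers for it can also amplify those. The submitters' processing notes name fastp, a read filtering and trimming tool, with no version. The denoiser, the classifier, the reference taxonomy and any filter on rare sequences are not given in the sources used here.

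One table was analysed. Per the file headers it has 3 columns, which hold an identifier, a taxonomy string and a confidence for each sequence variant (an exact amplicon sequence, ASV, taken as a proxy for a bacterial strain or gene copy). It lists 961 variants. The confidence, as deposited by the authors, is a fraction between 0 and 1 that gives the classifier's certainty in the taxonomy string. It is not an abundance. The rank to which it refers is not given in the sources used here, so confidences of strings that stop at different ranks were not tested against each other. No column or row of this table belongs to a sample. The number of reads behind each variant and each sample is therefore unknown, no depth or read-based detection limit is given, and no mean, standard deviation or test between the 4 groups was computed. A count test per genus and per variant, diversity indices and a test of community composition had been fixed for the case of counts per sample before the data were examined. They were replaced by the description that had been fixed for a table of taxonomy alone. A mouse gene table supplied as a reference was not used here.

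Each string was split into kingdom, phylum, class, order, family, genus and species. A rank was called named where it held a name other than a placeholder (unidentified, uncultured, metagenome, gut bacterium or incertae sedis). Ranks without a name were divided into empty fields, where the string goes on but the name is blank, and ended strings, where the string stops above that rank. Names were used as deposited. Shares are percentages of all 961 variants with exact (Clopper-Pearson) 95% binomial intervals. These intervals cover counting error only, and they treat variants as independent although copies of the gene within 1 genome are not. Whether intervals of different taxa overlap is described below, but this is not a test of their difference. A share of variants is a measure of how many distinct sequences a taxon has, not of how many cells.

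The rule for the taxa named in the text was fixed before the data were examined. It took every phylum, every class with at least 5 variants, and the 10 orders, 15 families and 25 genera with the most variants, with ties at the last place kept, together with the members found of 13 lists of genera. These lists were also written before the data were examined and cover 99 distinct genera, 15 of which are in more than 1 list. Plastid and mitochondrial variants were counted as a further class. The alternatives were minimum confidences of 0.8, 0.9 and 0.95, shares of the variants named at the rank in place of all variants, placeholder names counted as names, removal of plastid, mitochondrial, archaeal and unassigned variants, and bracketed or numbered genus names merged with the plain name. In the closing section, differences of medians were tested with 100000 permutations, and rank correlations across variants were given bootstrap intervals from 2000 draws.

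The parser, the counts and the permutation test were tested on simulated data with 961 variants. All 8 of the 8 known counts were recovered. Over 200 simulated orders of the list, the permutation test called 7% of those with no effect and 98.5% of those in which the numbers of 46 members were raised by 300. Fewer permutations were used in this check than in the closing section. Sets of other sizes were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.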

Results

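The bacterial content of mouse stool was surveyed by sequencing part of the 16S rRNA gene in a study of asthma treated with Shegan-Mahuang decoction (SMD), a herbal preparation. The design had 15 mice in each of 4 groups. The groups were a control group, a model group, an SMD group and a group given prednisone, a glucocorticoid. In each group, 6 stool samples were labelled for sequencing. This design asks how the model differs from the control, and whether SMD or prednisone changes the model's community. The table analysed here lists each sequence variant once for all 24 samples together, with its taxonomy and the confidence of that taxonomy, so those comparisons between groups were not analysed here. The values below describe the catalogue of 961 variants of the 24 samples as a whole. A share is a share of distinct variants and says nothing about how abundant a taxon was.

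Firmicutes and Bacteroidota, the phyla that dominate the mammalian gut, held most of the catalogue. Firmicutes had 715 variants, which is 74.4% of the 961 (95% interval 71.5 to 77.1). Bacteroidota had 146 variants, or 15.2% (13.0 to 17.6). The intervals of these phyla did not overlap. Proteobacteria followed with 21 variants (2.19%, 1.36 to 3.32) and Actinobacteriota with 14 (1.46%, 0.799 to 2.43), and the intervals of these last phyla did overlap.

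The other 12 phyla had at most 3 variants each. Patescibacteria, very small bacteria that live on other cells, had 3 variants, all in Candidatus Saccharimonas. Cyanobacteria also had 3 variants, and all of them were placed in Chloroplast, the order that collects plant plastids. Campylobacterota and Deferribacterota had 1 variant each, Helicobacter hepaticus and Mucispirillum schaedleri, which are both residents of the mouse intestinal mucus. Their confidences were 0.960 and 0.989. Fusobacteriota had 1 variant, a Fusobacterium, at a confidence of 0.718. Chloroflexi and Desulfobacterota had 1 variant each, at 0.928 and 0.918.

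Archaea had 8 variants (0.832%, 0.360 to 1.63) in 5 phyla. Aenigmarchaeota had 3 of them, Nanoarchaeota 2, and Euryarchaeota, Halobacterota and Crenarchaeota 1 each. The Euryarchaeota variant was a Methanobrevibacter, a methane producer of animal guts, at a confidence of 0.766. The Aenigmarchaeota variants had confidences between 0.728 and 0.769, whereas both Nanoarchaeota variants and the Crenarchaeota variant had between 0.9979 and 0.9994.

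Within Firmicutes, the class Clostridia held 615 variants, or 64.0% of the catalogue (60.9 to 67.0), and Bacilli held 92 (9.57%, 7.79 to 11.6). All 146 Bacteroidota variants were in the class Bacteroidia and the order Bacteroidales. Gammaproteobacteria had 16 variants, Coriobacteriia 9 and Alphaproteobacteria 5. Of these 5, which are also among the 21 Proteobacteria, 3 were placed in Mitochondria, at confidences of 0.795 to 0.999. The other 2 were a Sphingomonas and a variant without a named order. Lachnospirales was the order with the most variants, at 366 (38.1%, 35.004 to 41.240), ahead of Bacteroidales and of Oscillospirales with 130 (13.5%, 11.4 to 15.9). Orders known mainly from sequences followed, namely Clostridia UCG-014 with 53 variants and the Clostridia vadinBB60 group with 41. RF39 and Bacillales had 25 variants each, Erysipelotrichales had 18, Lactobacillales 17 and Peptostreptococcales-Tissierellales 10.

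At family level, Lachnospiraceae, anaerobes that ferment plant polysaccharides, had 364 variants, or 37.9% of the catalogue (34.8 to 41.0). Muribaculaceae, a Bacteroidales family typical of the mouse gut, had 129 (13.4%, 11.3 to 15.7). Oscillospiraceae had 74 (7.70%, 6.09 to 9.57) and Ruminococcaceae 44 (4.58%, 3.35 to 6.10). The intervals of these 4 families did not overlap, except those of Oscillospiraceae and Ruminococcaceae, whose bounds both round to 6.1%. Bacillaceae, aerobic spore formers, had 22 variants and Erysipelotrichaceae 13. Anaerovoracaceae and Eggerthellaceae had 9 each, Christensenellaceae 8 and Tannerellaceae 7. Erysipelatoclostridiaceae, Halomonadaceae, Lactobacillaceae, Peptococcaceae, Prevotellaceae and Staphylococcaceae had 5 each. These 16 families held 709 variants, or 73.8% of the catalogue, and 26 of all 57 named families had a single variant.

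**Figure D1:**
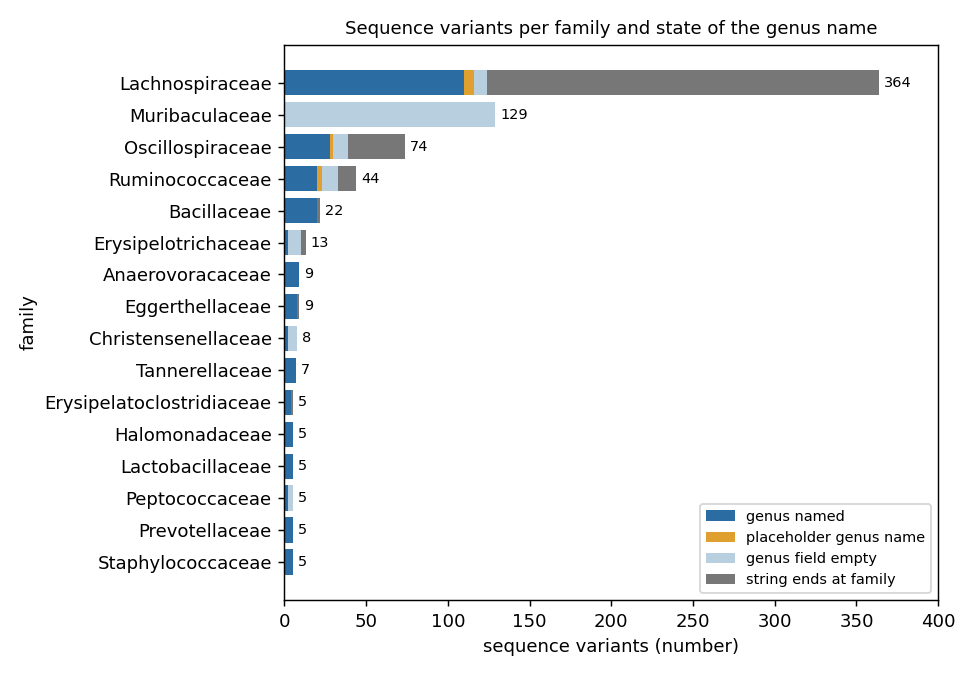
Horizontal bars give the number of sequence variants in each of the 16 families with the most variants, divided by whether the genus is named, a placeholder, an empty field or absent because the taxonomy string ends at the family; the number at each bar is its total. Lachnospiraceae has 364 variants, 240 of them with strings that end at the family, and all 129 Muribaculaceae variants have an empty genus field.

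A genus was named for 287 variants, or 29.9% (27.0 to 32.9), in 90 genera, of which 42 had a single variant. The family was named for 776 variants (80.7%, 78.1 to 83.2) and the phylum for 915 (95.2%, 93.7 to 96.5). Among the variants without a genus name, 311 had an empty field, 348 had a string that ended higher up and 15 had a placeholder. The Lachnospiraceae NK4A136 group, a part of that family common in mouse stool, had the most variants of any genus, at 34 (3.54%, 2.46 to 4.91). Their median confidence was 0.801, and 4 of the 34 had a confidence of at least 0.9, against 8 of 15 in Bacillus, so that this first place was lost at that limit. Bacillus came next with 15 variants (1.56%, 0.876 to 2.56). Its interval overlapped that of the NK4A136 group, but the difference of these counts was not tested.

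Other Lachnospiraceae among the most frequent genera were GCA-900066575 with 11 variants, Acetatifactor with 10, Roseburia and Lachnospiraceae UCG-001 with 8 each and Blautia with 7. A2, Lachnoclostridium, Lachnospiraceae UCG-006 and Marvinbryantia had 5 each. The Lachnospiraceae FCS020 group and the Eubacterium xylanophilum group had 3 each. In Oscillospiraceae and Ruminococcaceae, Colidextribacter and Oscillibacter had 11 each, Ruminococcus 6, Anaerotruncus and Harryflintia 5 each and Intestinimonas 3. Butyricicoccus, of the neighbouring family Butyricicoccaceae, had 3, and so did the Eubacterium brachy group of Anaerovoracaceae. Enterorhabdus, the genus name on 8 of the 9 Eggerthellaceae variants, belongs to a family that transforms plant compounds and steroids. Parabacteroides had 7 variants, 6 of which carried the species name Parabacteroides goldsteinii at confidences of 0.957 to 0.996. Halomonas, a salt-tolerant genus, had 5 variants. Atopostipes, Ligilactobacillus, Staphylococcus and Streptococcus had 4 each. Bacteroides, Candidatus Saccharimonas and Erysipelatoclostridium had 3 each.

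The lists of genera fixed beforehand drew on named genera only, so they cover 81 variants (8.43%) and 25 of the 99 listed genera. Membership goes by genus name alone, so it does not show that a variant has the trait of its list. No comparison of a list between groups was made. Of 17 butyrate producers, 6 were found, with 31 variants (3.23%, 2.20 to 4.55). These were Oscillibacter with 11 variants, Roseburia with 8, Lachnoclostridium with 5, Butyricicoccus and Intestinimonas with 3 each and Subdoligranulum with 1. The species field did not always match these genus names. Judged by their confidences, 3 of the Lachnoclostridium variants were labelled Dorea sp. 5-2. The Roseburia variants with the lowest and highest confidence were labelled Eubacterium sp. 14-2 and Clostridium sp. Clone-44. With a minimum confidence of 0.9 the list kept 7 of its 31 variants, and all 8 Roseburia variants had a confidence of 0.874 or less. With bracketed and numbered names merged with the plain name, the butyrate list had 7 genera and 42 variants. Of these, 11 stood under bracketed Eubacterium names. Of 12 other producers of short-chain fatty acids, the fermentation products that feed the gut lining, 6 were found with 26 variants. Blautia and Parabacteroides had 7 each, Ruminococcus 6, Bacteroides 3, Alistipes 2 and Dialister 1.

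Of 6 genera listed as mucin degraders, 4 were found with 17 variants, namely Parabacteroides, Ruminococcus, Bacteroides and Mucispirillum. The 6 Ruminococcus variants, all in Ruminococcaceae, and the Bacteroides variants are also counted among the fibre degraders. No variant was named Akkermansia, the best known genus of that list. The list of lactic acid bacteria and bifidobacteria had 4 of 12 genera and 11 variants, with 4 in Ligilactobacillus, 4 in Streptococcus, 2 in Enterococcus and 1 in Lactobacillus. No variant was named Bifidobacterium. The list of mouse gut Bacteroidales had 4 of 14 genera and 14 variants, which leaves out the 129 Muribaculaceae variants because these carried no genus name. The list of bile acid transformers had 3 of 8 genera and 5 variants. Bacteroides had 3, and Turicibacter and Lactobacillus had 1 each. With bracketed and numbered names merged with the plain name, this list had 5 genera and 17 variants, of which 11 were in bracketed Eubacterium groups. Those groups were placed in Lachnospiraceae, Anaerovoracaceae and Ruminococcaceae, and whether they transform bile acids was not tested. Fibre degraders had 2 of 6 genera and 9 variants, in Ruminococcus and Bacteroides.

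Of 16 listed Enterobacterales and relatives, only Escherichia-Shigella was found, with 1 variant at a confidence of 0.971. Helicobacter was found and Campylobacter was not. Neither of the 2 names of segmented filamentous bacteria, which induce T-helper responses in the mouse ileum, was found, and none of 4 listed sulfate reducers was. Whether rare sequences were filtered out is not given in the sources used here, and most variants had no genus name. A name that was not found therefore does not show that the organism was absent. For some names the higher ranks were not found either. No variant was placed in Verrucomicrobiota, the phylum of Akkermansia, or in Bifidobacteriales, the order of Bifidobacterium. The only Desulfobacterota variant was in the order Bradymonadales, and the only Clostridiales variant was named Clostridium sensu stricto 1. The 46 variants without a phylum stay open. Among 4 gut archaea, Methanobrevibacter was the only one found, with 1 variant. Among 17 reagent and skin genera, 3 were found with 6 variants (0.624%, 0.229 to 1.35). Staphylococcus had 4, and Micrococcus and Sphingomonas had 1 each. Plastids had 3 variants and mitochondria 3, together 0.624% of the catalogue (0.229 to 1.35).

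The median confidence of the 961 variants was 0.9989 (order-statistic 95% interval 0.9984 to 0.9992), with quartiles of 0.912 and 0.9999. A confidence of at least 0.9 was reached by 737 variants (76.7%, 73.9 to 79.3), and 0.8 by 846 (88.0%, 85.81 to 90.02). No kingdom was given for 20 variants (2.08%, 1.28 to 3.20), and 26 more had a kingdom and no phylum. The 20 unassigned variants had a median confidence of 0.592, and all 941 assigned variants had a confidence above 0.7. Strings that ended at the family had a median of 0.9997 over 294 variants, while strings that ended at the kingdom had a median of 0.868 over 26. Median confidences differed among the larger families. Muribaculaceae had 0.9997, Lachnospiraceae 0.9994, Oscillospiraceae 0.968 and Ruminococcaceae 0.902, and the ranks to which these strings ran differed as well.

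**Figure D2:**
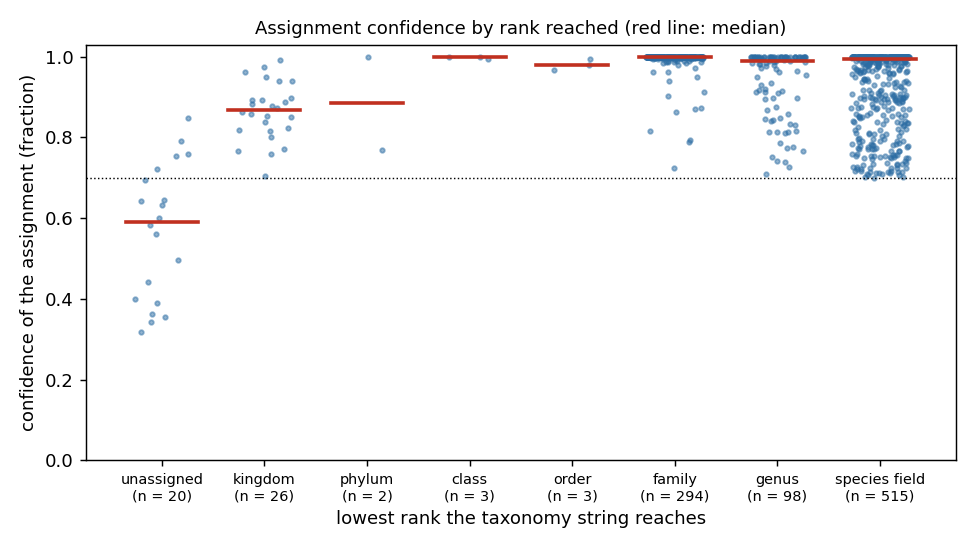
Each point is 1 sequence variant, placed by the lowest rank that its taxonomy string reaches (horizontal axis, with the number of variants) and by the confidence of the assignment (vertical axis, a fraction); red lines are medians and the dotted line lies at 0.7. All 941 assigned variants lie above 0.7, and the 20 unassigned variants have a median of 0.592.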

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

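The order of the phyla and of the larger families rests on numbers of variants, and most alternatives moved shares by less than their intervals. Of 118 recomputed values, 91 stayed within the interval of the reported value (or within 1.5 times a reported count), 13 moved higher and 14 lower. Some of the 91 could not have changed, such as lists with no variant found. Main results were the shares of Firmicutes, Bacteroidota, Lachnospiraceae and Muribaculaceae, the share named at genus, the median confidence and the butyrate list. Of their 25 recomputed values, 15 stayed, 7 moved higher and 3 lower. As a share of the variants named at the rank, Firmicutes rose from 74.4% to 78.1%, Lachnospiraceae from 37.9% to 46.9% and Muribaculaceae from 13.4% to 16.6%, because fewer variants form the denominator. With a minimum confidence of 0.9, Bacteroidota took 19.5% and Muribaculaceae 17.5%, and with 0.95 they took 21.0% and 18.8%. All 129 Muribaculaceae variants passed both limits while the total fell to 737 and 687. The share of variants named at genus fell from 29.9% to 20.6% at 0.9, and the butyrate producers from 31 variants to 7. The median confidence was 0.912 over the 295 variants named at genus or species, against 0.9989 over all and 0.9997 over strings that ended at the family. A minimum confidence therefore took out more of the variants with a genus name. The rank that a confidence refers to is unknown, so effects of these limits cannot be separated from how far the strings ran. Of the other 17 moved values, 6 were higher and 11 lower. They include Clostridia as a share of the variants named at class (68.0%). Of the 287 variants named at genus, the Lachnospiraceae NK4A136 group held 11.8%, Bacillus 5.23% and Ruminococcus 2.09%, over 3 times their shares of all variants. At minimum confidences of 0.9 and 0.95, Oscillospirales took 9.77% and 9.02%, Oscillospiraceae 5.56% and 5.53%, and Ruminococcaceae 3.12% and 2.47%. At 0.9 the Lachnospiraceae NK4A136 group had 4 variants and Bacillus 8, and at 0.95 they had 2 and 7, so the NK4A136 group lost its first place among genera. Merging bracketed and numbered names took the list of bile acid transformers from 5 to 17 variants, 11 of them under bracketed Eubacterium names. This rise comes from the merge of names and does not show more bile acid transformers. Counting placeholders as names does not alter a share held by a named taxon, and it moved the share named at genus to 31.4%, within its interval. No paired analysis was possible because the table used here has no values per sample, and for the same reason the tests between groups and the omission of single replicates were not run. The depth of sequencing is unknown, so how complete the catalogue is cannot be stated.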

Other observations

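All tests in this part except the correlation of number and confidence within Lachnospiraceae were chosen after the table had been seen.

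The catalogue also held genera reported from salt-rich, alkaline or other habitats outside animals. A set of 11 such genera, picked after the names were seen, had 21 variants. Their habitat was not tested, and some of these genera may also live on or in animals. Halomonas had 5, Atopostipes 4, Aliidiomarina, Dietzia and Oceanobacillus 2 each, and Alcanivorax, Jeotgalicoccus, Methanoregula, Ornithinibacillus, Pseudogracilibacillus and Thiobacillus 1 each. Their confidences ran from 0.872 for Methanoregula to above 0.9999 for a Dietzia variant. Species names were given to 31 variants under 18 names. The spore former Bacillus sporothermodurans, known from heat-treated food, had 3 variants, and Bacillus coagulans, Bacillus oleronius, Bacillus ruris and Bacillus thermoamylovorans had 1 each. The confidences of these 7 variants lay between 0.732 and 0.878. Streptococcus danieliae, first isolated from a mouse, had 3 and Roseburia intestinalis 2, at confidences of 0.821 to 0.896 and of 0.755 to 0.778. For 7 variants under 4 names, the genus in the species name differed from the genus field. Adlercreutzia mucosicola and Adlercreutzia muris stood under Enterorhabdus, Blautia coccoides under the Lachnospiraceae NK4A136 group, and Clostridium leptum under UCG-009 or a placeholder. A further 21 variants had a strain or culture label in the species field, under 17 labels. These were left out of that comparison, so the 7 are not all the differences. For example, 3 variants were labelled Dorea sp. 5-2, and no variant had the genus name Dorea.

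Variants are numbered from 0 to 960 without gaps, and the number was related to the taxonomy. The 46 variants without a phylum had a median number of 822.5, and none of them was among the first 120. Their median lay 365.5 places later than that of the others, further than in any random order drawn (two-sided permutation p = 1.0e-05, the smallest that the permutations can give). This lateness was seen before the test was chosen, so the p-value describes the pattern and is not independent support for it. The list was not sorted by falling confidence, since Spearman's rho of number and confidence was 0.12 (0.05 to 0.19) across the 776 variants named to family and 0.12 (0.03 to 0.21) across the 364 Lachnospiraceae variants, and variants are not independent replicates. The 14 plastid, mitochondrial and archaeal variants also came late, by 251 places at the median (permutation p = 0.022). A number that follows falling abundance may account for both, but without read counts it cannot be told apart from an order by the number of samples.

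Genus names were missing in 2 ways, and the 2 families with the most variants each showed mainly 1 of them. All 129 Muribaculaceae variants carried an empty genus field (100%, 97.2 to 100). A confidence limit would not give this, unless shortened strings were later filled with empty fields. Of the 248 Lachnospiraceae variants without a name or placeholder, 240 had a string that ended at the family (96.8%, 93.7 to 98.6). A blank name kept as an empty field would not give this, but a reference entry that stops at the family would. How the strings were written out is not given in the sources used here, so the 2 patterns do not exclude either cause. Other families showed both kinds of missing name, with 10 empty fields and 11 ended strings in Ruminococcaceae and 9 and 35 in Oscillospiraceae. A candidate explanation is that names were blank in the reference or blanked afterwards for Muribaculaceae, while Lachnospiraceae genera are too alike in the sequenced stretch to be told apart above the classifier's limit. Neither the reference nor the sequences were used here, so this stays a hypothesis. No Muribaculaceae variant and 110 of the 364 Lachnospiraceae variants carried a genus name.

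Of the 8 archaeal variants, 4 had a confidence under 0.8, against 88 of 907 bacterial variants with a phylum. Misplacement of poorly matching sequences may account for those 4. Low confidence was not shared by all, since 3 of the 8 (37.5%) had a confidence of at least 0.99. Misplacement at high confidence was not tested, so these 3 are not shown to be archaea. DNA from reagents or surroundings stays open. The fixed reagent and skin list had 0.624% of the variants, most of them in Staphylococcus, which mouse skin and stool also carry, and no blank sample is among the 24 samples. A biological source was not tested. Separately, 5 of the 20 unassigned variants had a confidence of 0.7 or more, and all assigned variants lay above that value. What the confidence of an unassigned string refers to is not given in the sources used here. Whether a limit on confidence decided which variants got a kingdom can therefore not be told.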
